A study of Mus musculus with 8 samples.

How the data were processed

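Gene expression was measured with Affymetrix mouse microarrays in total RNA of the aorta from 8 samples, 4 of mutant and 4 of control mice. Groups were taken from the labels, and replicates were numbered in the order of the samples within a group, so equal numbers in the 2 groups pair nothing. RNA was extracted with a kit for fibrous tissue and biotinylated cRNA was made by the manufacturer's standard method, per the labels' protocols. The deposited table holds log2 values per probe set, from 0.9 to 15.82 with 2 decimals. GCOS is the tool named in the submitters' processing notes, without a version. How background was corrected and how arrays were normalized and summarized is not given in the sources used here. The log2 scale was read from the range of the deposited values, and the quartiles of the 8 arrays were nearly equal, so the arrays had been put on a common scale before deposit. No 2 arrays held the same values: the closest pair shared 24.7% of values to 2 decimals.

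The table has 45037 probe sets. The platform annotation gave 1 gene symbol for 34945 of them, several for 932 and none for 9160, and no symbol changed when updated through the gene identifier. Probe sets with several symbols were not named. Values were used as deposited. The 40% of probe sets with the lowest mean over the 8 arrays were left out (lowest mean kept 2.97), which left 27023 probe sets and 12173 genes. For gene lists and named genes, each gene was represented by the probe set with the highest mean over the 8 arrays. Values of other probe sets are given for Srf, Acta2, Myh11, Synpo2, Fam189a2 and Mmrn2, and those of other genes are not described.

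The test was limma 3.58.1 in R 4.3.3, with genotype and set as terms, a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment over the probe sets tested, at a threshold of 0.05. Differences are mutant minus control on the log2 scale, so 1 is a 2-fold change. SE is limma's moderated standard error. The design, the alternatives, 22 gene lists and the rule for named genes were chosen before the data were examined. The named genes are Srf, Tagln, up to 10 genes rising and 10 falling most among those that pass (as none passed, the 10 with the smallest p, named as not passing), and up to 4 genes with the smallest p from each list. Any other gene given with a value was chosen after its values were seen. The 22 lists hold 498 genes, of which 461 had a probe set named in the annotation used. Of the lists, 21 were tested and the sex-linked list is given as values. List tests were camera with a preset correlation of 0.01 as the main test, camera with an estimated correlation, and fry, with adjustment over the 21 lists. The preset correlation gives small p-values when genes of a list move together, so the p with an estimated correlation is given beside each call of these lists, and none of those calls held with it. Fry tests whether the genes of a list move one way on balance, and none of the 21 lists passed in the fit reported. Its mixed test, for change in either direction, gave an adjusted p of 0.0454 for the contractile, actin, endothelial and fibroblast lists. Counts "over the list alone" adjust p-values within that list. Some lists share genes, such as Klf4, Vcam1, Lum, Dcn and Ppp1r14a, and such a gene can pass over a list alone and not over another.

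Lists were included for the cell types a dissected aorta can hold beside smooth muscle, since a difference in dissection changes their share in whole-tissue RNA. Alternatives were no filter and a stricter filter, quantile normalization, median centring, no set term, other variance models, each array left out in turn, and each set alone. Weights per array were added after mutant 2 was seen to stand apart. Lists of interferon response, sympathetic neuron and antibody genes were added after the genes with the smallest p, or those highest in single arrays, had been seen. They are used in the closing observations, where the members already seen are counted apart for the interferon and sympathetic lists. No per-sample column was left unused.

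The procedure was tested on 5 simulated tables of 27023 probe sets. The residual spread of each probe set in the fit was taken as its true spread, so the rates are approximate. Each table held 200 changed probe sets and, beside them, the contractile list shifted by -0.25. Of the 200, the procedure recovered 24.8% of those changed by 0.5 on the log2 scale, 62.4% at 1 and 90.4% at 2. There were 7 false calls per table on average. Of unchanged probe sets, 5.22% had an unadjusted p under 0.05. The simulated genes varied independently of each other, unlike those of a tissue. Figures were drawn with Python 3.11.15.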

Results

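The series measured messenger RNA in the aorta of 4 month-old mice in which the gene of serum response factor (SRF) had been deleted in smooth muscle cells, and in the aorta of littermates that kept it. SRF is a transcription factor that binds control regions of many muscle and cytoskeleton genes. The mutants carried the floxed Srf gene and a tamoxifen-inducible Cre recombinase placed in an allele of Tagln, the gene of the smooth muscle protein SM22. The controls carried the floxed gene. Mice of both groups received 1 mg of tamoxifen by intraperitoneal injection for 3 days and were killed 8 days after it. There were 8 arrays, 4 per group, each made from 2 ug of total RNA. Their titles number 2 sets of 4 arrays, each with 2 controls and 2 mutants. Set 1 holds controls 1 and 2 and mutants 1 and 2, and set 2 holds controls 3 and 4 and mutants 3 and 4. What the set number stands for is not given in the sources used here. The labels do not say whether each array came from a separate mouse, so p-values measure only the spread between these arrays, which may be technical.

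The arrays had similar distributions, with medians of 3.72 to 3.98 on the log2 scale, and their number limits the precision. Among the 7 arrays other than mutant 2, correlations across probe sets were 0.992 to 0.997 within a set and 0.983 to 0.988 between sets. Mutant 2 correlated with the other 7 arrays at 0.961 to 0.974. The sets differed at an adjusted p under 0.05 in 21.4% of the probe sets tested, 2932 higher and 2864 lower in set 2, and the set entered the limma fit as a term.

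The first value to give is that of the targeted gene. Srf, in the brighter of its probe sets, was at 10.30 ± 0.17 in controls (log2 value, SD, n = 4) and at 10.10 ± 0.38 in mutants. The difference of -0.20 (SE 0.19, 95% confidence interval -0.64 to 0.24) lay within the spread between arrays (limma adjusted p = 0.686), and a two-sided exact permutation test of 4 against 4 arrays gave p = 0.5143, where the smallest possible is 0.0286. The controls were at 10.52, 10.20, 10.15 and 10.34 and the mutants at 10.21, 9.54, 10.32 and 10.34. The difference was -0.48 in set 1 and 0.08 in set 2. Without mutant 2, the lowest array, it was -0.01. The other probe set of Srf differed by -0.03 (SE 0.15). The part of Srf that was deleted and the place of these probe sets relative to it are not given in the sources used here, so the values do not check the deletion.

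No gene passed the adjusted threshold between mutant and control aorta, and those with the smallest p are named here as not passing. Ppp1r14a, which encodes an inhibitor of myosin phosphatase, was at 13.24 ± 0.26 in controls and 12.66 ± 0.26 in mutants, a difference of -0.59 (SE 0.06, adjusted p = 0.102). Ptprz1, a receptor-type tyrosine phosphatase, differed by -0.96 (SE 0.09, adjusted p = 0.1). Osmr, the receptor of the cytokine oncostatin M, differed by 0.67 (SE 0.06, adjusted p = 0.1). Sox18, a transcription factor of endothelial cells, differed by 1.25 (SE 0.17) and Ptprb, an endothelial phosphatase, by 1.00 (SE 0.13). The cell adhesion molecule Mcam differed by -0.73 (SE 0.08). The other 4 of the 10 genes with the smallest p were Ces5a (-0.80), Pwwp3b (-0.83), Tstd3 (-0.65) and Rhpn2 (0.78). All 10 had the same sign in both sets, which choosing the smallest p over both sets favours, so it is not separate support. They were taken over the brightest probe set of each gene. Dimmer probe sets of Synpo2 (-1.19, adjusted p = 0.1, and -0.87, adjusted p = 0.185), Fam189a2 (0.78, adjusted p = 0.14) and Mmrn2 (0.96, adjusted p = 0.328) had p values below the highest of the 10. The first of the Synpo2 probe sets had an unadjusted limma p of 4.95e-06, below those of all 10 (lowest 1.27e-05, Osmr). Over the 27023 probe sets tested with limma, 0 passed an adjusted p of 0.05, and 0 genes passed with a 2-fold change. At an unadjusted p under 0.05 there were 2581 probe sets, 1217 higher and 1364 lower in mutants, where chance gives 1351. Such probe sets numbered 1426 without control 1, 1279 without the set term and 2944 without mutant 1. With each array centred on its median, these were 955 higher and 1666 lower, and that centring moved the median difference of all genes from -0.02 to -0.09. Leaving out control 3 gave 10 genes, all higher in mutants and 9 of them at least 2-fold, among them C2 (2.61), Scara5 (1.96), Tgfbi (1.66) and Ms4a4d (1.61). Leaving out any other array gave 0.

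Most of the smooth muscle contractile genes tested were lower in the mutant aorta, in arrays in which the endothelial, fibroblast and leukocyte lists had higher medians (0.93, 1.02 and 1.15). Of 30 contractile genes, 27 were lower and 3 higher, and the median difference was -0.25. As a list they passed camera with a preset correlation of 0.01 (adjusted p = 2.95e-08) but not with an estimated correlation (adjusted p = 0.294). Adjusted over the list alone, 7 fell: Ppp1r14a, Tagln, Myh11, Cnn1, Tpm1, Myl6 and Ppp1r12b. Over all genes tested, 0 passed. Myh11, the smooth muscle myosin heavy chain, fell from 14.69 ± 0.04 to 14.48 ± 0.06 (difference -0.21, SE 0.05) in its brightest probe set. Its dimmer probe set, which was not part of the list test, differed by -0.51 (SE 0.12). Over all probe sets tested, both had a limma adjusted p of 0.384. Cnn1, the actin-binding protein calponin, fell from 14.26 ± 0.22 to 13.87 ± 0.18 (difference -0.40, SE 0.10). Tagln fell from 15.32 ± 0.04 to 15.03 ± 0.11 (difference -0.29, SE 0.05), but an allele of Tagln holds the Cre in the mutants, and the effect of that insertion on this value was not tested. The lowest differences belonged to genes that did not pass, the intermediate filament gene Des (-0.78, SE 0.30) and the actin gene Actg2 (-0.68, SE 0.23), and the highest was that of Ndufa4l2 (0.80), also not passing. These were named after their values were seen. Acta2, the smooth muscle actin gene, was at 15.37 in controls and 15.36 in mutants in its brightest probe set, close to the highest value in the table (15.82), where differences can be compressed, a limit that Tagln and Myh11 share. Its other probe sets, not part of the list test, differed by -0.77 and -0.76, neither passing over all probe sets tested. The 4 probe sets of Synpo2, an actin-binding protein of muscle, differed by -0.48 in the brightest and by -1.19, -0.87 and -0.80 in the others. None of the 4 passed over all probe sets tested.

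Fry gave the contractile list an adjusted p of 0.0771 in the fit reported. The fry adjusted p was 0.0368 with no filter, 0.00785 without mutant 2, 0.0412 in set 2 alone and 0.0141 with array weights. In no other setting did the list pass fry, and in none did it pass camera with an estimated correlation. The list's median was -0.30 in set 1 and -0.14 in set 2. Without Tagln, 6 of 29 fell and the camera adjusted p was 1.36e-07, and 0.294 with an estimated correlation. The number that fell depended on the arrays and on the setting: 13 without mutant 2, 10 without mutant 1, 7 without control 2, and 1 without any of controls 1, 3 and 4 or mutants 3 and 4. It was 14 with array weights, a setting added after the data were seen, 12 with the stricter filter on dim probe sets, 2 without the mean-variance trend, 1 after median centring and 0 without the set term.

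**Figure D1:**
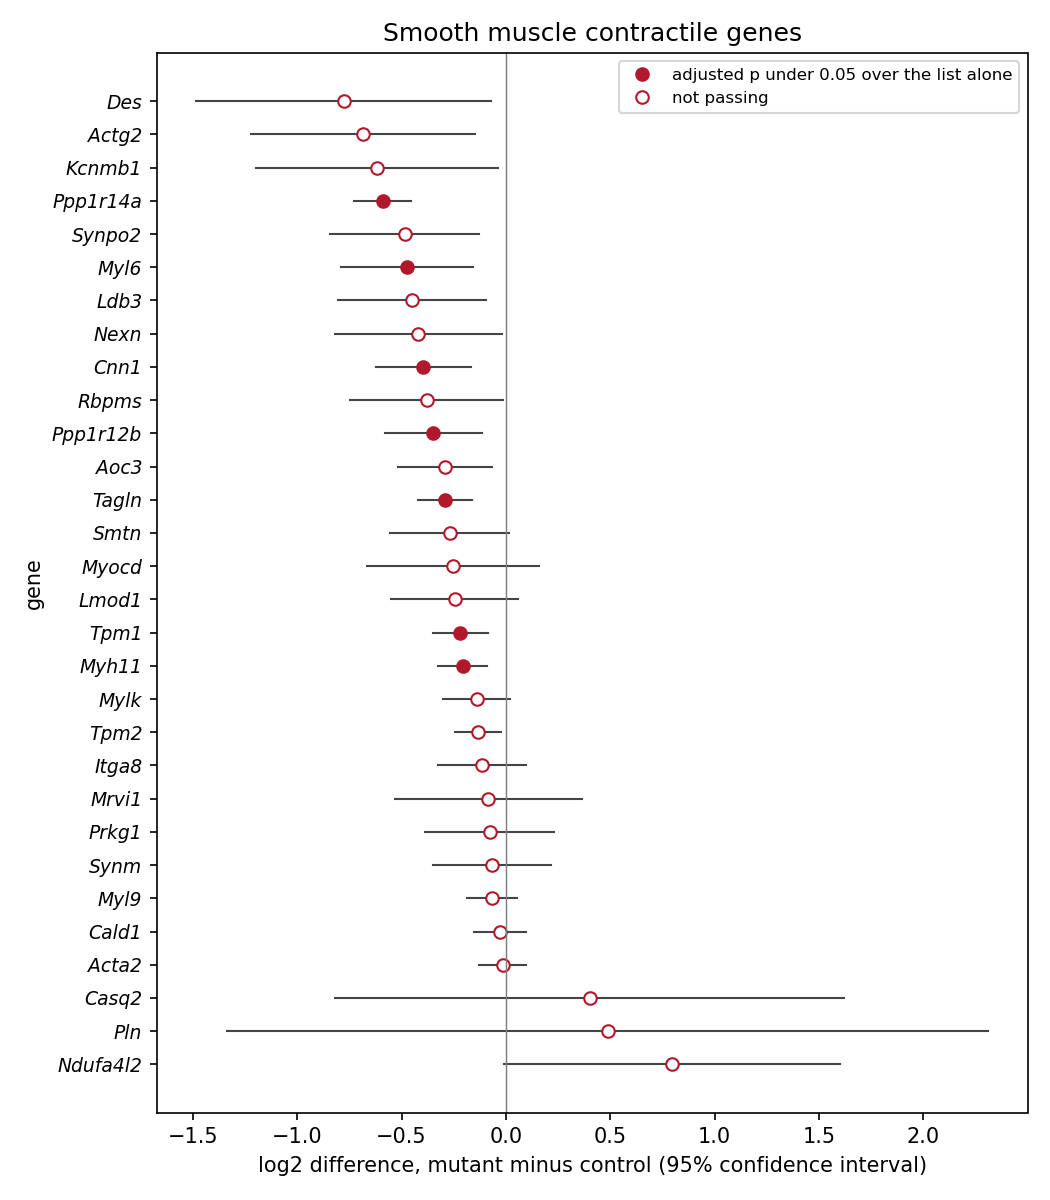
Log2 difference between mutant and control aorta (horizontal axis, 4 arrays per group, set term in the fit) for the 30 contractile genes tested, with 95% confidence intervals as lines and filled points for the 7 genes that passed over the list alone. A reader should see that 27 points lie below 0 and that Acta2 lies at -0.02.

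Most tested genes of cell adhesion to the matrix and of contraction signalling were lower too. Their falls were not tested against those of the contractile genes, and Ppp1r14a, Pln and Prkg1 are in both the contractile and the channel list. In the list of integrins and focal adhesion, 31 of 37 genes were lower, the median was -0.20 (-0.12 without mutant 2 or with array weights) and 0 passed over the list alone or over all genes. Its lowest p values belonged to Tln1 (talin, -0.31, SE 0.07), Itgb3 (integrin beta 3, -0.54, SE 0.15), Lama4 (a laminin chain, -0.34, SE 0.11) and Sgcb (a sarcoglycan, -0.34, SE 0.12). The camera adjusted p was 4.61e-05, and 0.485 with an estimated correlation. In the list of channels, receptors and contraction signalling, 24 of 33 genes were lower, with a median of -0.13, which was -0.04 without mutant 2, -0.06 with array weights, -0.09 with no filter and -0.20 with median centring. Adjusted over the list alone 3 fell, Ppp1r14a, the calcium-activated potassium channel Kcnma1 (-0.46, SE 0.09) and the calcium channel Cacna1c (-0.53, SE 0.12), and over all genes 0. Avpr1a, a vasopressin receptor, went the other way (1.04, SE 0.30) and did not pass. The camera adjusted p was 0.00867, and 0.546 with an estimated correlation. This count was 5 without mutant 2, 2 without mutant 4, 1 without any of controls 1 to 4 or mutant 3, and 0 without the set term. In set 1 and set 2 the medians were -0.28 and -0.10 for integrins and focal adhesion, and -0.21 and -0.07 for channels and signalling.

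Although fry's mixed test gave an adjusted p of 0.0454, the list of actin cytoskeleton genes and widely expressed SRF targets did not pass camera. Its median was -0.08 over 40 genes (camera adjusted p = 0.367), and was -0.05 without mutant 2, -0.13 without mutant 3 and -0.16 with median centring. Pdlim7, a cytoskeletal adaptor, fell over the list alone (-0.62, SE 0.10), and over all genes 0 passed. The number that fell was 2 without control 2 or mutant 2, and 0 without control 4, mutant 3 or the set term, and 1 or 2 genes rose without control 1, control 3 or mutant 1. With the stricter filter 4 rose and 4 fell, and with array weights 5 rose and 4 fell. Non-muscle myosin Myh9 differed by 0.36 (SE 0.09) and Filip1l by -0.36 (SE 0.10), neither passing. Immediate-early genes, many of which SRF controls in stimulated cells, did not pass either. The median of 24 was -0.03 and the mean 0.05 (camera adjusted p = 0.577). It was 0.05 in set 1, where 3 genes rose (camera adjusted p = 0.0215 in that set alone, and 0.756 with an estimated correlation), and -0.10 in set 2 (adjusted p = 0.0329, and 0.566 with an estimated correlation). The interaction adjusted p was 0.000199, and 0.58 with an estimated correlation. The lowest p values over both sets had Klf4 (0.84), Klf2 (0.99, SE 0.31), Jund (-0.16, SE 0.06) and Ier3 (-0.58, SE 0.24), none passing. The sign of this list's median turned when control 1, control 3, control 4, mutant 1 or mutant 3 was left out (highest 0.06), and 1 gene rose without control 3.

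Markers of synthetic or modulated smooth muscle did not pass as a list (median 0.06 over 19 genes, camera adjusted p = 0.103), but passed in several other settings. These were no filter (0.06, adjusted p = 0.0267), array weights (0.12, adjusted p = 0.0156), set 2 alone (0.20, adjusted p = 0.0143), without control 1 (0.08, adjusted p = 0.0281), without mutant 2 (0.13, adjusted p = 0.0091) and median centring (adjusted p = 0.0324), where the median turned to -0.01. With an estimated correlation the adjusted p in these 6 settings was 0.478, 0.324, 0.513, 0.421, 0.261 and 0.56, in the same order. Over the list alone 3 rose, the adhesion molecule Vcam1 (0.75, SE 0.16), Cytl1 (1.03, SE 0.23) and the transcription factor Klf4 (0.84, SE 0.20), and over all genes 0. The count was 1 without mutant 2 and 0 without any of controls 1, 2 and 4 or mutants 1 and 4. Extracellular matrix genes did not pass (median -0.06 and mean 0.03 over 43 genes, camera adjusted p = 0.577). The matrix proteases Mmp2 (0.55, SE 0.15) and Mmp3 (1.26, SE 0.35) and the proteoglycan genes Lum (1.32, SE 0.38) and Dcn (1.01, SE 0.24) had the lowest p values there, and 0 passed, although 5 rose without control 3, and 5 rose and 2 fell with array weights. Lum and Dcn are in the fibroblast list too. The median of the matrix list was 0.05 without mutant 2. It was -0.22 in set 1 and 0.06 in set 2 (interaction adjusted p = 0.00522, and 0.866 with an estimated correlation).

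Markers of endothelial cells were higher in the mutant aorta. Of 16 tested, 15 were higher, the median was 0.93 and 10 rose over the list alone, 0 over all genes. The endothelial receptor Tek rose from 7.94 ± 0.40 to 9.08 ± 0.81 (difference 1.14, SE 0.22), and the nitric oxide synthase Nos3 from 7.92 ± 0.15 to 9.03 ± 0.49 (difference 1.10, SE 0.21). Vwf, the von Willebrand factor gene, differed by 0.96 (SE 0.19) and Ptprb by 1.00. The single lower gene was Erg (-0.28), named after its value was seen. The list passed camera (adjusted p = 1.21e-10) but not with an estimated correlation (adjusted p = 0.294). The median was 1.27 in set 1 and 0.42 in set 2 (0.26 without control 4), and this difference between sets passed an interaction test with the preset correlation (adjusted p = 2.12e-06) and not with an estimated correlation (adjusted p = 0.58). The count was also 10 without mutant 2 and was 2 without the set term.

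Markers of adventitial fibroblasts, the connective tissue cells of the outer vessel wall, were higher too. Of 14 tested, 13 were higher, with a median of 1.02. Over the list alone 11 rose and over all genes 0. Scara5 rose from 8.90 ± 0.90 to 10.48 ± 0.14 (difference 1.58, SE 0.33), Dpt by 1.03 (SE 0.21), Cd34 by 1.22 (SE 0.27) and Pi16 by 0.92 (SE 0.20). The camera adjusted p was 1.04e-09, and 0.294 with an estimated correlation. The medians were 1.30 in set 1 and 0.79 in set 2, the latter 0.22 without control 4 and 1.27 without control 3. Without mutant 2 the count was 12, and without control 2 or mutant 1 it was 7. Control 3 lay above the other controls in the list mean, at 0.37 against -0.87 to -0.61 relative to the mean of all arrays.

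Macrophage and other leukocyte markers were higher in all 19 genes tested, with a median of 1.15. Over the list alone 13 rose and over all genes 0. Among them were the macrophage receptors Cd163 (1.02, SE 0.23) and Csf1r (0.85, SE 0.23), the endotoxin co-receptor Cd14 (1.26, SE 0.30) and the complement gene C1qb (0.80, SE 0.20). The camera adjusted p was 1.43e-11, and 0.294 with an estimated correlation. The median was 1.94 in set 1 and 0.37 in set 2 (interaction adjusted p = 1.47e-14, and 0.475 with an estimated correlation). In set 2 it was 0.06 without control 4 and 0.60 without control 3, and the list mean of mutant 3 (-0.18) lay below that of control 3 (-0.14). The count was 0 without any of controls 1, 2 and 4 or mutants 1 and 2. Inflammatory mediators had a median of 0.36 over 12 genes, with 10 higher (camera adjusted p = 0.000339, and 0.294 with an estimated correlation), and of 0.22 without mutant 1 (camera adjusted p = 0.0159, and 0.447 with an estimated correlation). Over the list alone Vcam1 alone rose, and no gene did without control 2, control 4, mutant 1, mutant 2, mutant 4 or the set term, while 2 did without control 1 or control 3. With no filter 0 rose and with the stricter filter 3. Icam1 (1.42, SE 0.41) and the chemokine Ccl8 (1.70, SE 0.56) did not pass. The median was 0.57 in set 1 and 0.01 in set 2 (interaction adjusted p = 0.000165, and 0.475 with an estimated correlation).

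**Figure D2:**
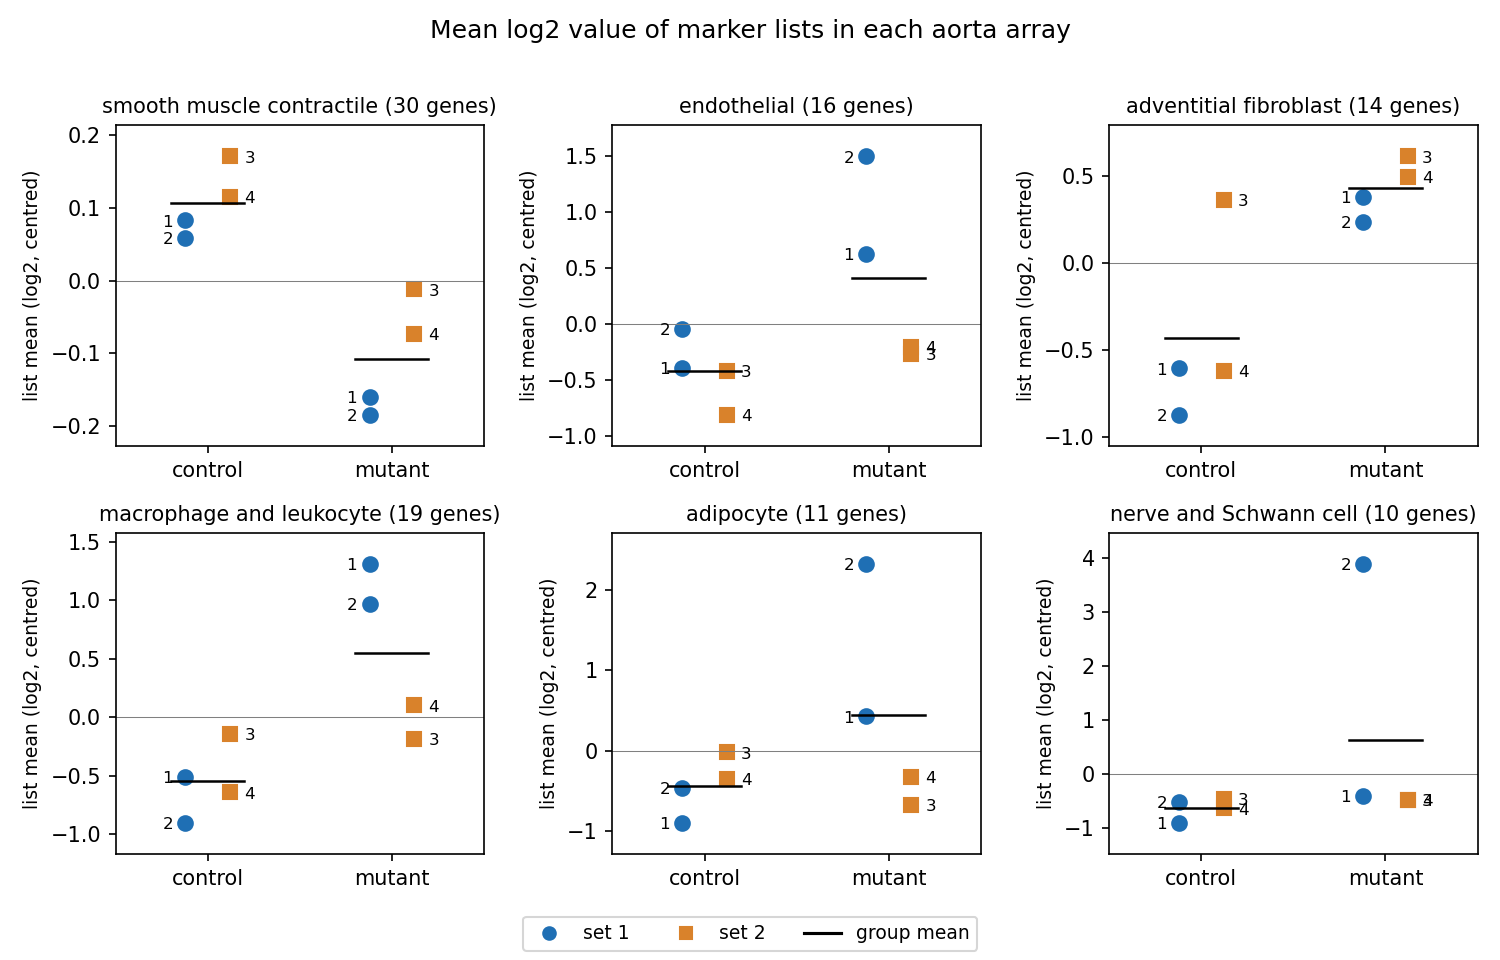
Mean log2 value of 6 marker lists in each array, relative to the list's mean over the 8 arrays (vertical axis), for control and mutant aorta, with circles for set 1, squares for set 2, replicate numbers beside the points and black lines for group means. A reader should see contractile means of 0.06 to 0.17 in controls and -0.18 to -0.01 in mutants, and mutant 2 alone at 3.88 in the nerve panel.

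Markers of fat and nerve differed between groups through few arrays. The adipocyte list had a median of 0.75 over 11 genes (camera adjusted p = 0.0027, and 0.595 with an estimated correlation), at 2.14 in set 1 and -0.40 in set 2, and of 0.34 (camera adjusted p = 0.172) without mutant 2, the highest array. The brown adipocyte list had a median of 1.03 over 8 genes (camera adjusted p = 0.0474, and 0.595 with an estimated correlation), at 3.08 in set 1 and -0.27 in set 2. Relative to the mean of all arrays, control 1 was furthest, at -2.46, and mutant 2 was at 1.94. The median was 0.26 without control 1, 0.31 without mutant 2, 1.58 without control 3, 1.81 without mutant 3 and 0.62 with array weights. Its call was lost without control 1, control 4, mutant 1, mutant 2 or mutant 4, and with array weights. Ucp1, the uncoupling protein of brown fat, differed by 4.20 in set 1, where it was at 6.83 and 9.43 in controls 1 and 2 and at 12.16 and 12.50 in mutants 1 and 2, and by -1.12 in set 2. The nerve and Schwann cell list had a median of 1.46 over 10 genes (camera adjusted p = 0.00691, and 0.595 with an estimated correlation), and of 0.0005 without mutant 2 (camera adjusted p = 0.822), 0.14 with array weights and 0.24 with the stricter filter. In none of these 3 lists did a gene pass over the list alone or over all genes.

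Of the other lists, blood cell genes had a median of 0.51 over 6 genes (camera adjusted p = 0.025, and 0.294 with an estimated correlation), a call lost without control 3, mutant 1 or mutant 4. With no filter the median was 0.13. Alas2, of haem synthesis, differed by 0.80 (SE 0.32) and Pf4, of platelets, by 1.02 (SE 0.43). Oxidative phosphorylation genes had a median of 0.21 over 27 genes (camera adjusted p = 0.00867, and 0.693 with an estimated correlation), at 0.57 in set 1 and -0.13 in set 2 (interaction adjusted p = 3.09e-09, and 0.58 with an estimated correlation). It was -0.02 without mutant 2, 0.02 with array weights, 0.11 without control 1, 0.32 without mutant 1 or control 3 and 0.14 with median centring. The call was lost without mutant 2, control 1 or control 2 and with array weights. Striated muscle genes had a median of -0.21 over 18 genes (camera adjusted p = 0.201). This list passed without mutant 2 (-0.50, adjusted p = 0.00706) or control 4 (-0.46, adjusted p = 0.0346), in set 2 alone (-0.39, adjusted p = 0.00702) and with array weights (-0.40, adjusted p = 0.0156), but with an estimated correlation the adjusted p was 0.314, 0.577, 0.513 and 0.374. The median turned to 0.06 without control 3. Cell cycle (median -0.05 over 17 genes, camera adjusted p = 0.406), apoptosis and p53 (0.00 over 16, adjusted p = 0.645), unfolded protein response (0.10 over 20, adjusted p = 0.154) and circadian clock (-0.15 over 16, adjusted p = 0.364) did not pass. The unfolded protein list passed without control 1 (0.17, adjusted p = 0.0264) or mutant 2 (0.16, adjusted p = 0.000288, 1 gene rising), in set 2 alone (0.14, adjusted p = 0.00341) and with array weights (0.15, adjusted p = 0.00398), but with an estimated correlation the adjusted p was 0.705, 0.261, 0.513 and 0.374. The clock list passed without mutant 4 (-0.34, adjusted p = 0.0164, and 0.521 with an estimated correlation) and turned to 0.02 without mutant 3. With all arrays, no gene of these lists passed over its list alone. The Y-linked genes Kdm5d, Eif2s3y and Uty were at 7.24, 10.05 and 6.16 in controls and differed by -0.12, -0.05 and -0.01.

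The sets share no arrays, and their differences were compared, although the labels do not say whether the sets came from separate mice. Across 12173 genes, which are not independent replicates, the difference in set 1 correlated with that in set 2 at Pearson's r = 0.25 and Spearman's rho = 0.24, and 55.5% of genes had the same sign. Without control 4, r was 0.08. A set-by-genotype interaction passed an adjusted p of 0.05 in 14 probe sets, and 1384 had an unadjusted p under 0.05 where chance gives 1351. Contractile genes were lower in both sets (interaction adjusted p = 0.268), and the endothelial, fibroblast and leukocyte medians were above 0 in both, in set 2 by amounts that depended on control 4. Each set holds 2 against 2 arrays, and single arrays moved other set medians too. Without mutant 2 those of set 1 were 1.02 (adipocyte), 1.70 (brown adipocyte), 0.01 (nerve), 0.13 (oxidative phosphorylation), -0.12 (integrins) and -0.07 (channels). Without control 1 that of brown adipocyte genes was 1.77. Without mutant 3 those of set 2 were -0.05 (adipocyte), 0.16 (brown adipocyte), -0.04 (integrins) and 0.11 (inflammatory). Adjusted over the list alone within each set, 0 contractile genes fell in set 1 and 8 in set 2, while 10 endothelial, 10 fibroblast and 17 leukocyte genes rose in set 1 and 0 of each in set 2. Adipocyte genes had a median above 0 in set 1 and below 0 in set 2 (interaction adjusted p = 5.94e-10, and 0.58 with an estimated correlation).

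**Figure D3:**
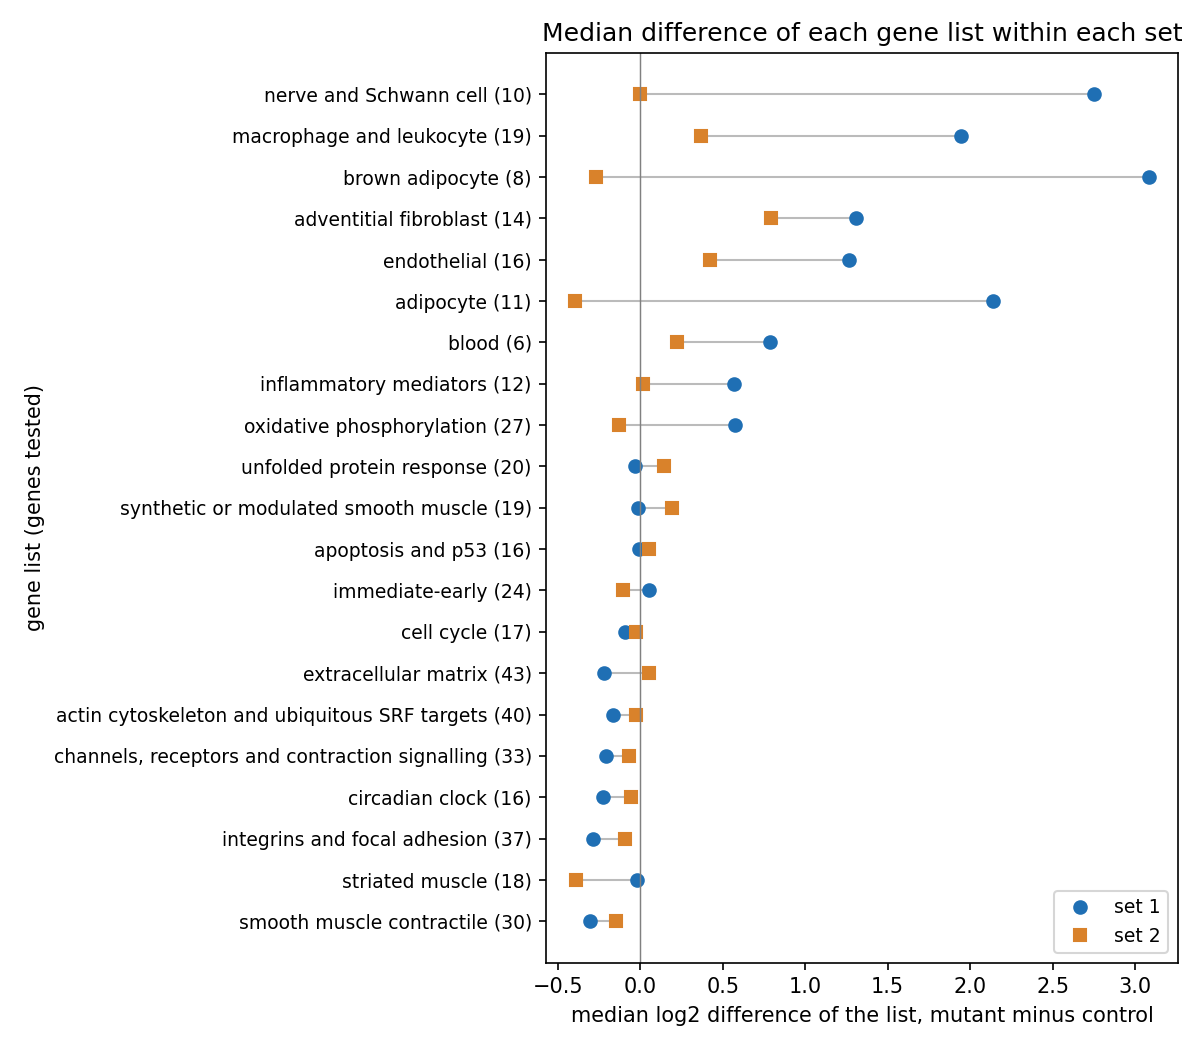
Median log2 difference, mutant minus control (horizontal axis), of each of the 21 gene lists tested, computed within set 1 (circles) and set 2 (squares), 2 against 2 arrays each, with the number of genes in brackets. A reader should see the contractile list below 0 in both sets and the adipocyte list at 2.14 in set 1 and -0.40 in set 2.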

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

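The counts over other splits of the arrays were planned, and the splits within sets and the tests of nerve tissue and of tissue composition were chosen after the result was seen. In groups of 4 arrays, an array was picked out when its gap to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value. This happened 23 times in 220 groups, where chance gives about 5%. Mutant 2 was highest for the mean of the nerve and Schwann cell list (9.35, others 4.99 to 5.06), Mbp (12.88), Cdh19 (9.25), Igfbp3 (8.96) and Ndufb5 (12.3), and lowest for Srf (9.54) and Mybpc2 (4.74). Mutant 1 was highest for Cacna1c (8.27), Klf4 (10.78), Myh11 (14.57), Nr1d1 (9.69) and Rhpn2 (8.0), and lowest for Avpr1a (4.38) and Dpt (11.66). Mutant 4 was highest for Cd34 (10.91) and lowest for Mylpf (3.3). Control 2 was lowest for the mean of the blood list (5.18), Pf4 (6.69), Ccl8 (3.62) and Tnnt1 (5.74). Control 1 was highest for Mylpf (4.31) and lowest for Ndufb5 (11.15), and control 3 was lowest for Mcm4 (7.93).

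The mean of the nerve list was high in mutant 2 alone. Of the 10 tested members of the fixed nerve and Schwann cell list, 5 (50%) were over 3 log2 units higher in mutant 2 than the median of the other 7 arrays, among them Mbp (12.88), Prph (10.91) and Th (9.92), with a median excess of 4.49, a share that leaves nervous tissue in that sample open as the source. A list of sympathetic neuron markers, tested first, gave 18 of 19 (94.7%; 2 of the 19 are in the nerve list too). All except 3 had been seen to be high before it was written, and of these 3 there were 2 over that bound, so that share does not test the source. As a description, these neuron transcripts were high in mutant 2 alone, with a median excess of 7.14. Relative to the mean of all arrays, their list mean was 6.08 there and -1.03 to -0.72 in the others. Genotype would raise the list in mutants 1, 3 and 4 as well, but their median difference from controls was 0 (upper quartile 0.30) against an excess of 4.49 in mutant 2 (lower quartile 1.69), which argues against genotype as the source (a first bound, set on the spread around 0 and not on the size to be explained, had left it open). Nervous tissue taken along with that aorta may be the source and stays open.

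The contractile genes were lower while markers of several other cell types were higher. A smaller share of smooth muscle RNA in the mutant samples could give this without a change in any cell. It would lower all contractile genes by a common amount if smooth muscle alone expressed them. Whether other cells in the samples express some members was not checked, so unequal falls would not argue against composition. The falls of the 18 members with a mean under 13 were unequal (Cochran Q 51.6), but 2 of the 34 splits of the arrays, the real one included, were as unequal (highest other 175.7, which crosses the sets), and of the 18 splits within sets the real one alone was (next 44.83), too few to go below a share of 0.0556. It also raises the other cell types alike: the means of the endothelial, fibroblast, leukocyte and adipocyte lists differed between groups by 0.83, 0.87, 1.10 and 0.87, a range of 0.27 that 32 of 34 splits reached or passed, although within set 2 they were 0.38, 0.68, 0.35 and -0.31, and without mutant 2 the means over both sets were 0.57, 0.86, 1.02 and 0.26, a range of 0.76. A first form of this test, fibroblast against adipocyte list, gave an exact permutation p of 1 and could not have gone below 0.0556. Means of the nerve, blood and striated muscle lists differed by 1.26, 0.59 and -0.31, and these lists were not part of the range. The likeness therefore holds for the 4 chosen lists only. Composition and an effect of SRF loss, or of Cre, within smooth muscle cells cannot be told apart here, and these effects were not tested.

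Chance was examined by fitting all 34 splits of the arrays into groups of 4 that the set term allows, the real one included (the split by set itself could not be fitted). The 0 genes called were matched by 34 of 34, which any split must do, so this count does not bear on chance. The 2581 probe sets at an unadjusted p under 0.05 were reached by 5 of 34 splits, the highest other being 4906, so that share does not exclude chance. The 4 splits above it each set mutant 2 apart from the rest of set 1, a structure of the samples. For the contractile list 1 of 34 splits, the real one, gave a camera p as small (5.61e-09, next 7.09e-06), and for the endothelial list 1 of 34 (1.15e-11, next 2.68e-09). For the fibroblast list it was 2 of 34 (1.49e-10, smallest other 1.19e-19), for the leukocyte list 3 of 34 (6.8e-13, smallest other 2.9e-16) and for integrins and focal adhesion 2 of 34 (1.1e-05, smallest other 7.9e-06), so these shares do not exclude chance. Arrays of a set deviated together, so the splits that place 2 arrays of each set in each group are the closer comparison, and the share of 34 that was first to decide does not allow for this. There are 18 of them, which are too few for a share under 0.05 (smallest 0.0556). As many or more genes came from 18 of the 18, which a count of 0 again fixes in advance. For the other results 1 of 18, the real one, was as large, except 2 of 18 for the leukocyte list.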

How the results depend on the processing

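Array weights were chosen after seeing the data, and the other settings were planned. Fits with a smaller or larger pseudocount were not run, as the values were already log2. Unless a construction is named, the cause of a change was not tested.

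Genes passing numbered 0 in the fit reported, and 0 with no filter, a stricter filter, quantile normalization, median centring, no set term, other variance models and each set alone. Leaving out arrays gave 0 to 10, and 0 to 9 at 2-fold, with 10 and 9 without control 3. Array weights, which give mutant 2 a weight of 0.155, called 9 genes, 3 of them at 2-fold (higher Osmr, Fam189a2 and Sox18, lower Ppp1r14a, Ptprz1, Synpo2, Bdh1, Pwwp3b and Ces5a). Probe sets at an unadjusted p under 0.05 were 2581 as reported, 1279 without the set term (no replicate block), 1426 without control 1, 1485 in set 2 alone and 2944 without mutant 1. Arrays of the same set deviated together from their group means (control with mutant, r 0.07 to 0.66 in the same set, -0.63 to -0.11 between sets), so the set number marks a shared factor. The fit without that replicate block changed no list's call, but it lowered counts over the list alone by over 1.5 times for contractile, actin, channel, endothelial and inflammatory genes, as given with those results.

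In the fit reported, every list call was lost with camera's estimated correlation and with fry. The contractile list did pass fry in the settings given with that result. Medians were unchanged, at -0.25 (contractile), -0.20 (integrins), -0.13 (channels), 0.93 (endothelial), 0.75 (adipocyte) and 1.03 (brown adipocyte). The others were 1.02 (fibroblast), 1.15 (leukocyte), 0.36 (inflammatory), 1.46 (nerve), 0.51 (blood) and 0.21 (oxidative phosphorylation). With arrays left out, the contractile median ran from -0.28 to -0.18 and the endothelial from 0.71 to 1.09, all passing the preset test. Medians ran from 0.34 to 1.10 for adipocyte, 0.26 to 1.81 for brown adipocyte, 0.0005 to 2.12 for nerve, 0.38 to 0.59 for blood and -0.017 to 0.322 for oxidative phosphorylation, each losing its call in at least 1 case. The nerve call was lost at 0.24 with the stricter filter and at 0.14 with array weights, which also ended the brown adipocyte (0.62) and oxidative phosphorylation (0.0232) calls.

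Among reversals, a called list, oxidative phosphorylation, turned to -0.017 without mutant 2. In set 2 alone, 2 against 2 arrays, the called lists of adipocyte (-0.395, adjusted p = 0.00165, and 0.513 with an estimated correlation), brown adipocyte (-0.27), nerve (-0.0025) and oxidative phosphorylation genes (-0.13, adjusted p = 3.88e-06, and 0.513 with an estimated correlation) were also below 0. With both sets, the other reversals were in lists not called: apoptosis at 0.0025 with no filter, 0.003 with quantile normalization and 0.0468 with array weights (-0.059 to 0.0565 with arrays left out), modulated smooth muscle at -0.0075 with median centring, and with array weights immediate-early at 0.0053 and matrix at 0.0207. With arrays left out, immediate-early ran from -0.1595 to 0.0565, matrix from -0.142 to 0.048, striated muscle from -0.499 to 0.0595 and clock from -0.3405 to 0.023. Without a change of sign, actin ran from -0.1305 to -0.0495, modulated smooth muscle from 0.027 to 0.129, unfolded protein from 0.0135 to 0.171 and cell cycle from -0.082 to -0.028. The agreement of the sets ran from r = 0.0767 (without control 4) to 0.332. Genes that fell over the contractile list alone, 7 as reported, were 12 with the stricter filter, 2 without the mean-variance trend, 1 with median centring and 14 with array weights, and actin genes, 0 rising and 1 falling as reported, were 4 and 4 with the stricter filter and 5 and 4 with array weights. Dim probe sets near background and bright ones near the top of the scale limit what these arrays can show.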

Other observations

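The interferon and antibody lists below, and the tests on them, were chosen after genes of these lists had been seen among those with the smallest p or highest in single arrays.

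Genes induced by interferon were higher in the mutant aorta in both sets. Of a list drawn from general knowledge, 34 genes were tested, 0 of them in another list, and all 34 were higher, with a median of 1.09, at 1.44 in set 1 and 0.69 in set 2. In set 2 the list mean, relative to all arrays, was 0.178 in mutant 3 and -0.415 in mutant 4. It was -0.808 and -1.04 in controls 3 and 4. Values with arrays left out are not given for this list. Adjusted over the list alone 32 rose, and over all genes 0. Since 4 of the tested genes (Gbp3, Gbp6, Oasl2 and Oas1a) had been seen before the list was written, the 30 others are counted apart. They are correlated with the genes that led to the list, so their direction, counts and p values are not an independent test. All 30 were higher, 28 rose over the list alone, and the median was 1.03, at 1.36 in set 1 and 0.58 in set 2. Ifit1 differed by 2.42 (SE 0.51) and Iigp1 by 1.56 (SE 0.30). Tap1, which carries peptides for antigen presentation, differed by 1.51 and the transcription factor Irf7 by 1.03. Mx2 (0.00) and Mx1 (0.18) did not pass. For the 30 genes camera gave p = 1.16e-24 with the preset correlation and p = 0.0344 with an estimated correlation of 0.53, both unadjusted. In the comparison run first, their median lay above all 10000 random lists of the same size matched on mean level (highest 0.21), a comparison that ignores the correlation between these genes.

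The real split alone among 34 gave a camera p as small for the 30 genes (1 of 34, next 1.95e-19), which does not bear on chance, since these genes are correlated with those that led to the list in the real split, and since the 18 splits within sets allow no share below 0.0556. Leukocytes in the samples may raise interferon genes, and this stays open: in set 2 the interferon median was 0.69 and the leukocyte median 0.37 (0.065 without control 4 and 0.595 without control 3), but the mutant arrays of that set did not all lie above the controls once the leukocyte mean was subtracted. The mutants also differ from the controls by the Cre recombinase itself, which all mutant and, as far as the labels say, no control arrays carry, so deletion of Srf and the presence of Cre cannot be separated by this design.

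Antibody genes, a list of which 4 were tested, had a median difference of 4.15 in set 1 and -0.01 in set 2. Their mean was highest in mutant 1, at 5.43 relative to the mean over all arrays, followed by mutant 2 at 2.02 and control 2 at 0.61.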
